A study of Arabidopsis thaliana with 4 samples.

How the data were processed

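The data are 4 tables, 1 per library, that list per transcript its length, position, coverage, unique reads and RPKM. Per the labels' protocols, total RNA from roots was enriched for poly(A) RNA on oligo(dT) beads, fragmented, copied with random hexamers and sequenced on an Illumina instrument; no step that keeps strand is described, so reads of overlapping antisense genes cannot be told apart. The deposited read counts are whole numbers of uniquely assigned reads per transcript, per the file headers, and their sum in each table equals the total the authors used for scaling. The deposited RPKM values are those reads scaled by transcript length and by the library's total, per the file headers, and were recomputed from reads, length and total with no deviation beyond floating-point error. The deposited coverage is the percent of a transcript's length covered by reads, per the file headers. The aligner and the genome build are not given in the sources used here. Of 23381 loci, 23189 matched the TAIR10.1 gene table by locus code, and the file position of 23154 of these (99.8%) overlapped the gene there and lay within 2000 bp of its ends; printed coordinates are those of the files. A transcript absent from a table was taken as 0 reads.

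Reads and RPKM were summed over isoforms of a locus, which turned 26912 transcripts into 23381 loci. Because reads had to be unique, reads common to several isoforms of a locus appear to be missing: the 3089 loci with more than 1 isoform listed had a median of 0.986 RPKM, against 5.55 for the others, so levels of such loci (IRT1, JAZ1 and AT5G26270 among those named) are too low by an unknown amount. Reads of near-identical paralogs are affected in the same way. Each table lists only transcripts with at least 1 read. A locus with 1 isoform listed may therefore have further isoforms and lose reads as well.

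Each group has 1 library, so comparisons of 2 libraries carry no test. They are given as log2 ratios of RPKM + 0.5, which understates the change of weakly read genes, over the 17514 loci with at least 1 RPKM in at least 1 library. A gene was called higher or lower when its ratio was at least 2-fold and the 95% exact (Clopper-Pearson) counting interval of the read ratio, computed without the pseudocount, excluded no change. Because the exact interval has no pseudocount, it can lie beyond the ratio printed beside it for genes of few reads. For a difference of responses the size was 1 log2 unit. Its 95% counting interval was a normal approximation from reads + 0.5, centred on the printed difference, and not exact. PCR copies are not independent molecules, so intervals and floors cover counting error only. Folds against 0 reads use a floor of 3 reads per library. Al over both genotypes and genotype over both treatments were tested on summed read counts with edgeR's quasi-likelihood test (TMM factors, filterByExpr, both factors as additive terms, Benjamini-Hochberg adjustment), with 2 libraries per arm, 1 residual degree of freedom, a common dispersion of 0.0385 and 192.8 prior degrees of freedom. Nothing in the labels names separate cultures within a group, so these p-values measure only the spread left by the additive model. SE is the log2 fold change divided by the square root of its F value.

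Gene lists were fixed by locus code: 342 entries in 24 lists, of which 286 were measured past the filter, 39 lay below it and 17 had no read. They cover Al resistance, jasmonate biosynthesis, jasmonate signalling and turnover, jasmonate-responsive defence, tryptophan and indole glucosinolate synthesis, auxin, ethylene, cytokinin, tubulins and microtubule-associated proteins, wall loosening, iron deficiency, phosphate starvation, heat shock, touch and wounding, clock genes of morning and of evening phase, and markers of root hair, endodermis, root cap, xylem, phloem, dividing cells, green shoot tissue and seed storage. EXPA7 and EXPA18 stand on both the wall loosening and the root hair list. A list's median is given relative to the median of all genes, with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. Genes are named by a rule: the 8 highest and 8 lowest per comparison with at least 5 RPKM, up to 3 members per list with the largest change, and always COI1, ALMT1, MATE, ALS3, STOP1 and MYC2; some genes of the rule are left out for length. OPT3, FER1, F6'H1, CIPK23, TUA1, SPR1, CDKB2;2, ARR3, ARR4, AOC1, PS2, EB1C and OPCL1, genes that passed only with the length offset, and some members of the jasmonate signalling list, named for a small count, fall outside it. The groups, tests, lists, naming rule and the alternatives not marked as added were chosen before the data were examined.

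The alternatives were pseudocounts of 0.1 and 1, a filter of 5 RPKM or none, TMM or median-of-ratios factors applied to RPKM, a stricter interval rule, and for the tests DESeq2's size factors, DESeq2, limma-trend on log2 RPKM, no count filter and a model without the other factor. Removal of the length trend (a running median over 50 length bins), its combination with TMM factors, only loci with 1 isoform listed, a length offset in edgeR and random lists matched also on length were added after seeing the data. On simulated data for 16477 genes, the Al test found 34% of genes changed 2-fold and 100% of those changed 4-fold or more, with 6 false calls; the genotype test found 46% at 2-fold and 98% at 4-fold, with 11 false calls. The size rule, run on 16863 simulated genes for Al in Col, called 4% of genes changed 1.5-fold and 94% of those changed 3-fold, with 83 calls among unchanged genes. The size rule was simulated with counting error only, so the 83 calls do not estimate false calls between real libraries. For edgeR, every gene had a dispersion of 0.04 and 200 genes were changed alike in both genotypes or both treatments. No simulation held a length trend, and changed genes were drawn from the better-read ones. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used.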

Results

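Roots of Arabidopsis thaliana seedlings were profiled by RNA sequencing in the wild type Col and in coi1-2, a point-mutation allele of COI1, the F-box receptor for the hormone jasmonate. About 500 seedlings per sample, 6 days old, were kept in a dilute nutrient solution with 0 or 10 µM AlCl3. The sample titles and the treatment protocol give 6 h of exposure, whereas the series' design text gives 24 h, and the values do not settle which applies. The titles of the libraries without Al say 0 h, whereas the treatment protocol has them in solution with 0 µM AlCl3 for 6 h. If they were taken at the start, every Al ratio given here also includes time in solution, handling and time of day. The 4 groups, Col without Al, Col with Al, coi1-2 without Al and coi1-2 with Al, held 1 library each. The libraries held 7.80, 6.93, 7.42 and 7.19 M reads in that order (M, 1e6 reads), so a floor of 3 reads corresponds to 0.385, 0.433, 0.404 and 0.417 CPM. Comparisons of 2 libraries therefore have no replicate check and describe those libraries, with intervals that cover counting error only. A test across libraries was possible only for Al over both genotypes and for genotype over both treatments, with 2 libraries per arm. COI1 itself, on chromosome 2 from 16672493 to 16675748 on the reverse strand, was read at 33.9 RPKM in Col and 29.8 in coi1-2 without Al, and at 19.6 and 29.4 with Al. A point mutation need not alter the transcript level, so these values do not check the genotype labels.

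The test over both genotypes asked which root genes differed between the libraries with and without Al. ALMT1, the malate transporter that releases malate to bind Al outside the root, rose by 6.78 log2 units (SE 0.52, edgeR adjusted p = 7.41e-26), and PGIP1, an inhibitor of pectin-degrading enzymes, rose by 6.43 (SE 0.40, edgeR adjusted p = 9.98e-35). Genes that fell included some of iron acquisition, such as the ferric reductase FRO2 (log2 fold change -4.69, SE 0.36, edgeR adjusted p = 7.52e-26) and the iron transporter IRT1 (-2.90). Most markers of the endodermis (7 of 8) and of root hairs (6 of 8) fell, and all 13 tested genes of green shoot tissue rose. In the edgeR quasi-likelihood test on read counts, with genotype as a term, 4203 of 16477 genes rose and 4327 fell at an adjusted p of 0.05. The largest increases among genes with a mean of at least 5 RPKM included AT5G19880, a peroxidase (11.30), AT1G71140, a MATE-family efflux protein (10.68, SE 0.56, edgeR adjusted p = 2.32e-42), AT3G47480, an EF-hand calcium-binding protein (8.93, SE 0.45, edgeR adjusted p = 3.31e-44), ARD3, acireductone dioxygenase 3 (8.21), and LEA4-5, a late embryogenesis abundant protein (8.20). AT5G19880 had 0 reads in both libraries without Al, so its fitted value depends on the prior count and is no measure of size. The largest decreases included AT1G19900, a glyoxal oxidase-related gene (-6.45), AT3G19430 (-6.02) and CER4, an acyl-CoA reductase of wax and suberin synthesis (-5.91). Any difference in Al response between the genotypes counted as error in this fit, which left 1 residual degree of freedom and drew its spread from all genes.

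Of 16 tested members of the list of Al resistance genes, 10 rose and 1 fell, and 11 rose and 1 fell when adjusted over the list alone. BCB, a blue copper-binding protein, rose by 4.52 and ALS3, a transporter-like protein needed for Al tolerance, by 2.09, while the kinase gene CIPK23, named after its values were seen, fell by 0.92. ALMT1 was read at 0.0819 RPKM in Col and 0.258 in coi1-2 without Al, from 1 and 3 reads, and at 8.57 and 20.1 with Al, from 93 and 227 reads. MATE, a citrate transporter gene, was covered by 3, 2, 2 and 8 reads and the regulator gene STOP1 by 0, 0, 0 and 3, so neither could be compared. Whether depth or the restriction to unique reads left them so low was not tested. Of 14 iron deficiency genes 6 fell and 3 rose, with the same counts adjusted over the list alone; besides FRO2 and IRT1, the regulator BHLH38 fell by 3.58, while OPT3, FER1 and F6'H1, named after their values were seen, rose. Of 13 phosphate starvation genes 7 rose and 1 fell (7 and 1 adjusted over the list alone), with increases of IPS1, a non-coding RNA (1.97), PAP17, an acid phosphatase (1.64) and SPX3 (1.34), and a decrease of the phosphate transporter PHT1;1 (-1.07), whose reads are hard to tell from those of PHT1;2. Of 15 XTH and expansin genes, which loosen the cell wall, 6 rose and 4 fell (6 and 4 adjusted over the list alone). XTH24 rose by 4.94 and XTH23 by 3.36, whereas EXPA7, an expansin of root hairs, fell by 3.01. Of 22 tubulin and microtubule-associated genes 9 fell and 2 rose (9 and 2 adjusted over the list alone): MAP70-5 fell by 2.65, MAP65-2 by 2.30 and TUB5 by 2.25, and TUA1 and SPR1, named after their values were seen, rose. TUA2 and TUA4, both among the 9, share most of their sequence and cannot be counted apart with certainty.

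Markers of cell types also moved with Al, and these changes accompany every gene group given here. Of 8 endodermis genes 7 fell (7 adjusted over the list alone), led by CASP4, a protein of the Casparian strip (-3.03, SE 0.38, edgeR adjusted p = 2.32e-12), and PER64, a peroxidase of its lignin (-2.71). Of 8 root hair genes 6 fell (7 adjusted over the list alone), with COW1 at -3.32 and RSL4 at -1.83. Of 4 root cap genes 3 fell (4 adjusted over the list alone): FEZ by 1.70, BRN2 by 1.63 and CEL5 by 1.48. Of 10 genes of dividing cells and the meristem 6 fell and 1 rose (6 and 1 adjusted over the list alone), with CYCB2;1 at -1.87, CYCB1;1 at -1.67 and the cytokinesis syntaxin KNOLLE at -1.50. The 1 that rose was CDKB2;2, a cell cycle kinase gene named after its values were seen (0.67). Among 6 xylem genes CESA4 fell by 0.82, alone also when adjusted over the list alone, and of 2 phloem genes SUC2, a sucrose transporter, rose by 1.34, again the same count adjusted over the list alone. All 13 tested genes of green shoot tissue rose, also when adjusted over the list alone, with the light-harvesting protein genes LHCB1.1 at 4.51 (SE 0.37, edgeR adjusted p = 4.07e-23), LHCB2.2 at 4.31 and LHCB1.3 at 3.01. LHCB1.1 and LHCB1.3 are near-identical copies, as are the RBCS genes on this list, and the split between them is uncertain. No seed storage gene had enough reads to be tested.

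Hormone genes moved in both directions. Of 22 jasmonate signalling and turnover genes 5 rose and 5 fell (5 and 5 adjusted over the list alone): JOX4, an oxidase that inactivates jasmonate, rose by 4.68, as did JAZ7, JAZ12, CYP94C1 and JOX2 by less, and CYP94B1 and JAM1 fell by 2.05 and 1.92, as did MYC2, MYC4 and CYP94B3. Members of this list beyond 3 were named after their values were seen. Of 11 jasmonate biosynthesis genes KAT2 alone rose (1.48), also when adjusted over the list alone. Of 7 jasmonate-responsive defence genes 4 rose and 2 fell (4 and 2 adjusted over the list alone), with ANAC019 at 6.83, TAT3, a tyrosine aminotransferase, at 4.50 and ERF109 at -3.69. Among 22 genes of tryptophan and indole glucosinolate synthesis 8 rose and 4 fell (8 and 4 adjusted over the list alone), with CYP81F2 at 3.29, MYB122 at 2.34 and CYP79B3 at -1.89. Among 28 auxin genes 7 rose and 6 fell (6 and 6 adjusted over the list alone), led by GH3.3, an auxin-conjugating enzyme (4.04, SE 0.35, edgeR adjusted p = 3.03e-21). Among 21 ethylene genes 6 rose and 6 fell (6 and 6 adjusted over the list alone), with ACS8 at 2.22 and ACS5 at -2.65, both enzymes of ethylene synthesis. Of 12 cytokinin genes 5 fell and 2 rose (5 and 2 adjusted over the list alone), with the response regulator ARR8 at -2.09 and IPT3 at -1.77. ARR3 and ARR4, named after their values were seen, rose in this fit over both genotypes. By the size rule on RPKM without scaling factors, 0 of the 12 were called higher with Al in coi1-2 and 8 lower. Of 14 touch and wound response genes 6 rose and 4 fell (6 and 4 adjusted over the list alone), with ZAT12 at 3.29 and WRKY53 at -1.99. Of 4 heat shock genes ROF2 and HSP101 fell by 2.26 and 0.95, and of 6 evening clock genes ELF3 fell by 1.47 and TOC1 also fell, in both cases the same counts adjusted over the list alone; neither one-sided fall held with the length offset given below. The single morning clock gene tested did not pass. Long transcripts were lower with Al in both genotypes, and with that trend taken out as an offset, a choice made after seeing the data, edgeR found 3994 genes that rose and 3998 that fell; the counts became 11 up and 4 down for ethylene, 0 up and 5 down for cytokinin and 10 up for green shoot tissue. They turned from mostly up to mostly down for touch and wound genes (4 up, 6 down) and for wall loosening genes (6 up, 7 down), and the reverse for heat shock genes (2 up, 1 down). For the other lists that moved they were 5 up and 6 down for iron deficiency, 3 up for jasmonate biosynthesis, 4 up and 6 down for jasmonate signalling, 2 up and 2 down for evening clock genes, 9 up and 0 down for Al resistance, 9 up and 4 down for indole glucosinolates, 8 up and 1 down for phosphate, 1 up and 10 down for tubulins, 7 down for root hairs, 6 down for dividing cells and 0 for xylem. Members that passed only with the offset included, named after their values were seen, HSP70-4, HSP90.1, PRR5, GI, BTS, ABCG37, LOX6 and ACX1, which rose, and ELF4 and BRN1, which fell. Lists with unchanged counts, such as root cap and auxin, also exchanged members. Of the genes named above, CIPK23, CDKB2;2, CEL5, SPR1, JAZ7, ARR3, ARR4, HSP101, TOC1 and CESA4 no longer passed with that offset, and neither did further list members not named here. DESeq2 called 3149 genes that rose and 2515 that fell, and limma-trend on log2 RPKM, without scaling factors, called 2541 and 6418, a split far less even than that of edgeR.

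In Col the comparison of the Al library with the control library asks what Al alters in the wild type. The highest ratios belonged to AT3G47480, read at 0.647 RPKM without and 415.9 with Al (log2 ratio 8.50, 95% counting interval 7.78 to 11.61), AT3G46080, a zinc finger gene (7.32), PRX52, a peroxidase (7.31), AT4G36430, another peroxidase (6.98), and YLS9 (6.68). The lowest belonged to AT3G19430 (-6.35), FRO2 (517.9 against 6.71 RPKM, log2 ratio -6.17, interval -6.55 to -6.00), AT1G19900 (-5.52) and ST4B, a sulfotransferase (-4.93). Of 17514 genes past the filter, 2001 were at least 2-fold higher and 6264 at least 2-fold lower with Al, and the ratio over all genes had a median of -0.59. With TMM factors, which remove that shift, the split was 3881 higher and 3596 lower. Relative to all genes, the list median was highest for green shoot tissue (2.07 above, percentile 100 among 10000 random lists matched on expression) and lowest for the endodermis (-2.23, percentile 0). Jasmonate-responsive defence (1.39, percentile 99.1, but with 3 of 7 members higher and 2 lower) and Al resistance genes (0.77, percentile 98.0) stood high, and root hair (-0.92, percentile 0.81), iron deficiency (-0.85, percentile 0.53), dividing cells (-1.07, percentile 1.52) and tubulin genes (-0.63, percentile 0.01) stood low, though the bootstrap intervals over members included 0 for defence, iron deficiency and dividing cells. MYC2, a central regulator of jasmonate responses, was lower with Al (129.8 against 22.1 RPKM, log2 ratio -2.53). SESA4, the 1 seed storage gene past the filter, was read at 1.86 RPKM without Al and at 0 with Al, at least 2.96-fold lower against a floor of 3 reads per library.

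In coi1-2 the same comparison asks what Al alters when jasmonate perception is impaired. AT3G47480 (log2 ratio 7.57), LEA4-5 (7.21) and AT3G46080 (6.90) were again among the highest, and AT1G71140, with 0 reads without and 738 with Al, was at least 253.8-fold higher against a floor of 3 reads per library. AT3G22910, a P-type ATPase, was higher by 6.44. The lowest ratios included AT3G19430 (-6.27), AT1G19900 (-6.13), the peroxidase gene AT2G39040 (-5.78) and AT4G12520, a lipid-transfer-like protein (-5.24). In all, 1641 genes were higher and 4064 lower, with an all-gene median of -0.32, and with TMM factors 2585 were higher and 2571 lower. Relative to all genes, Al resistance (1.28, percentile 100), green shoot tissue (1.39, percentile 100), jasmonate-responsive defence (1.78, percentile 99.9) and phosphate starvation genes (percentile 98.5) stood high. The defence list rests on 7 of 16 genes, since VSP1, VSP2, the PDF1.2 genes, THI2.1 and CORI3 had no read. Of the 7, 4 were higher and 2 lower, and the bootstrap interval of its median, -1.98 to 2.30, included 0, as did those of wall loosening (4 of 15 higher, 6 lower) and dividing cells. Endodermis (-2.12, percentile 0), root hair (-1.92, percentile 0), cytokinin (-0.92, percentile 0.41), dividing cells (-0.75, percentile 2.03), wall loosening (-0.19, percentile 1.65) and tubulin genes (-0.49, percentile 0.01) stood low. Among lists matched also on length, an alternative added after seeing the data, jasmonate biosynthesis (98.21) and root cap genes (1.32) also lay at the outer ends. SESA4 had 18 reads without and 0 with Al, at least 5.82-fold lower against the same floor. PGIP1 was higher by 5.52, BCB by 4.87, ALMT1 by 4.77 and ALS3 by 1.44, and FRO2 was lower (297.7 against 16.2 RPKM, log2 ratio -4.16).

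**Figure D1:**
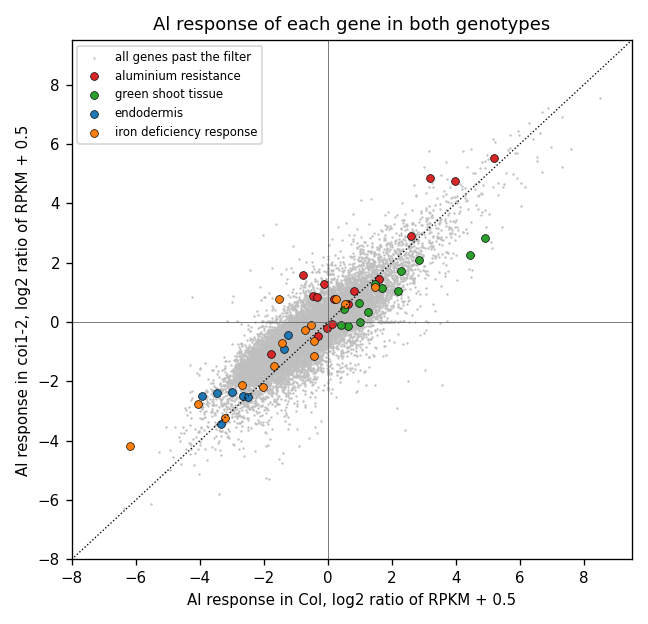
Log2 ratio of RPKM + 0.5 with over without Al for each gene past the filter, in Col on the horizontal axis and in coi1-2 on the vertical axis, 1 library per group, with members of 4 gene lists coloured and the dotted line marking equal ratios. The ratios follow each other (Pearson's r 0.850 across genes), with ALMT1 at 3.96 in Col and 4.77 in coi1-2 and FRO2 at -6.17 and -4.16.

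The responses of the genotypes overlapped. Across 17514 genes, which are not independent replicates, Pearson's r between the log2 ratios was 0.850, Spearman's rho 0.838 and the covariance 1.34; the ratios share no library. The genes higher with Al in both genotypes numbered 1234, where independent lists would share 187.5, and those lower in both 3504, where 1453.5 would be shared. Only 6 genes were called in opposite directions, and 11 with TMM factors. Over the 4 libraries, Al accounted for 83.3% of the summed squared contrasts, genotype for 9.61% and their interaction for 7.09%. With TMM factors the shared genes numbered 2168 higher and 1964 lower.

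**Figure D2:**
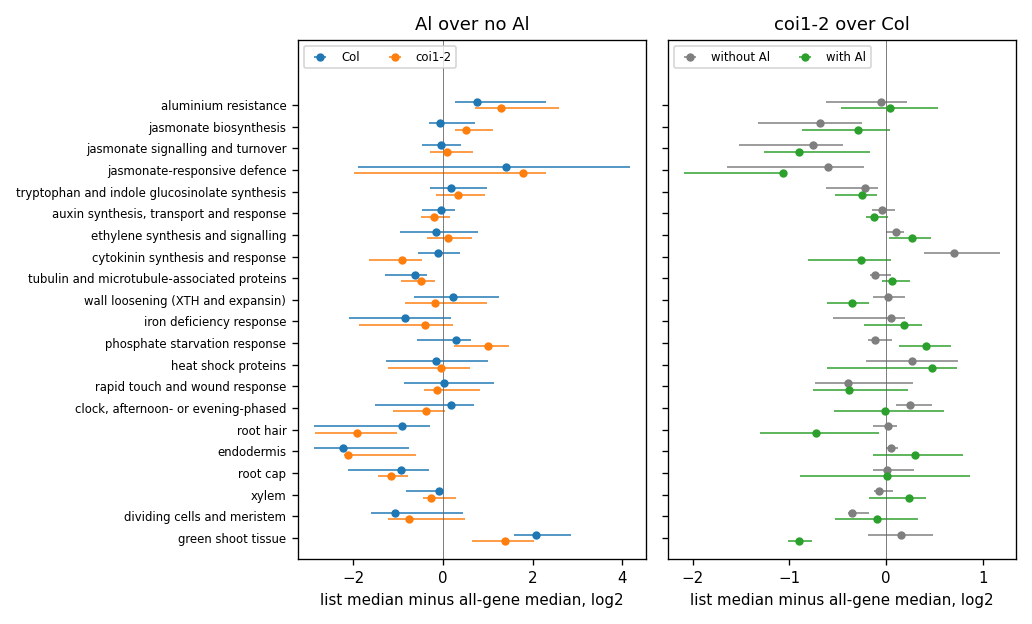
Median log2 ratio of each fixed gene list with at least 4 measured members, minus the median of all genes, for Al in each genotype (left) and for coi1-2 over Col in each treatment (right), 1 library per group. Bars are 95% bootstrap intervals over list members, not over samples; the endodermis list lies at -2.23 in Col and -2.12 in coi1-2, and jasmonate signalling lies at -0.76 without and -0.90 with Al.

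The comparison of genotypes asks which genes differ between coi1-2 and Col. No other mutant line was profiled, so an effect of COI1 cannot be told from other differences of the coi1-2 line. Over both treatments, some genes of jasmonate synthesis and breakdown were lower in coi1-2: the lipoxygenase gene LOX3 fell by 4.40 (SE 0.57, edgeR adjusted p = 1.32e-09), JOX4 by 4.14 (SE 0.46, edgeR adjusted p = 9.72e-13) and AOS, allene oxide synthase, by 1.21 (SE 0.28, edgeR adjusted p = 0.00914). AT4G29200, annotated as beta-galactosidase related on chromosome 4 from 14398054 to 14400198, fell by 7.45 (SE 0.43, edgeR adjusted p = 8.51e-37), from 62.2 and 104.2 RPKM in Col to 0.196 and 0.911 in coi1-2. In all, 26 genes were higher and 71 lower in coi1-2 by edgeR, and with the length offset 34 were lower, with JAZ1 and ANAC019 no longer among them. Other decreases were AT5G26270 (-4.59), TAT3 (-3.71), AT2G26380, a leucine-rich repeat protein (-3.64), and the transcription factors ERF109 (-2.60), ORA47 (-2.60) and ERF13 (-2.51). Increases were led by AT2G01422 (3.23, edgeR adjusted p = 2.48e-11), AT3G28510 (2.78) and GolS4, a galactinol synthase (2.00). Of 22 jasmonate signalling genes 5 fell, and 10 adjusted over the list alone, among them the repressor genes JAZ1 (-1.82) and JAZ6 (-1.45). Of 11 biosynthesis genes 2 fell (3 adjusted over the list alone), and of 7 defence genes 3 fell (5 adjusted over the list alone), namely TAT3, ERF109 and ANAC019. Among touch and wound genes WRKY40, ERF2 and ERF6 fell, by 1.34, 1.31 and 1.13, out of 14 tested, the same count adjusted over the list alone, but none of the 3 passed with the length offset. Among 16 Al resistance genes BCB fell by 1.96, alone also when adjusted over the list alone. No cytokinin or indole glucosinolate gene passed over all genes, though 2 of 12 and 2 of 22 passed adjusted over the list alone, higher and lower in coi1-2 respectively, and CYP79B2 and CYP79B3 were lower by edgeR with the length offset; no member of the remaining lists passed either way. By DESeq2 3 genes were higher and 13 lower, and AT2G01422 had an adjusted p of 1 there. With Al left out of the model edgeR called 0 genes in either direction, with 25 at an unadjusted p under 0.05 against 1318 in the full model. That model counts the Al effect as error, and Al held 83.3% of the summed squared contrasts, so its result says little about genotype.

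**Figure D3:**
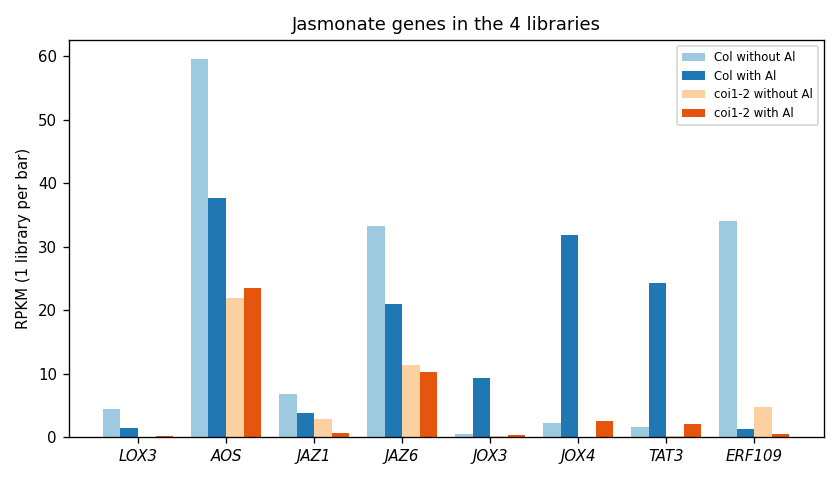
RPKM of 8 jasmonate-related genes in the 4 libraries, 1 bar per library, without error bars because each group has 1 library. All 8 are among the genes given as lower in coi1-2, so they do not stand for the jasmonate lists. Over both treatments edgeR called 5 of 22 signalling, 2 of 11 biosynthesis and 3 of 7 defence genes lower in coi1-2, and 0 higher. In coi1-2 the bars of AOS reach 22.0 and 23.5 RPKM, against 59.6 and 37.7 in Col.

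Without Al, part of the jasmonate genes were lower in coi1-2 than in Col, namely 11 of 24 of signalling, 4 of 12 of biosynthesis (LOX3, LOX4, AOS and AOC1, the last named after its values were seen) and 3 of 7 of defence. Of 12 cytokinin genes 4 were higher, ARR6, ARR8, CKX1 and IPT3. Of 16 Al resistance genes 3 were lower and 0 higher, though the list median lay near that of all genes (-0.05, percentile 26.54). The lowest ratios of coi1-2 over Col were those of AT4G29200 (-6.49), AT5G26270 (-3.86), GRX480, a glutaredoxin (-3.22), and BCB (16.5 against 2.02 RPKM, log2 ratio -2.75). AT2G01422 (5.54), AT5G26130 (3.22) and CBF3, a cold-response regulator (2.66), were among the highest. In all, 251 genes were higher and 235 lower, with an all-gene median of 0.01 and a split of 235 and 223 with TMM factors. Jasmonate signalling (-0.76, percentile 0), biosynthesis (-0.68, percentile 0), responsive defence (-0.60, percentile 0.1), touch and wound (-0.39, percentile 0), dividing cell (-0.35, percentile 0.14) and indole glucosinolate genes (-0.22, percentile 0.09) stood low relative to all genes. Of the touch and wound genes 3 of 14 were lower (WRKY40, ERF2 and ERF6) and 1 higher (CBF3), with a bootstrap interval that included 0, and of the dividing cell genes 0 of 10 were called. CYP79B3, an enzyme of indole glucosinolate synthesis, had a log2 ratio of -1.28. Cytokinin genes stood high (0.71, percentile 100), with ARR8 at 1.38, CKX1 at 1.25 and IPT3 at 1.22, as did evening clock genes (0.25, percentile 98.88), of which 0 of 6 were called.

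With Al, some members of these lists were lower in coi1-2: 5 of 24 of jasmonate signalling (JAZ1, JOX3 and JOX4, and, named after their values were seen, JAZ3 and JOX2), 2 of 7 of defence (TAT3 and ANAC019), 2 of 13 of green shoot tissue (RBCS1A and CA1) and 2 of 8 of root hairs (EXPA18 and PRP3). Jasmonate biosynthesis genes no longer stood apart (-0.28, percentile 13.3), with 2 of 12 lower (LOX3 and AOC2) and 1 higher (ACX1). AT4G29200 (-6.21), AT5G26270 (-4.48), JOX3 (9.36 against 0.401 RPKM, log2 ratio -3.45) and JOX4 (-3.43) were among the lowest, and AT3G28510 (2.53) and GolS4 (2.49) among the highest. In all, 1379 genes were higher and 328 lower; the all-gene median was 0.26, and with TMM factors the direction of this split turned, to 532 higher and 815 lower; with the length trend also removed it was near even, 392 and 372. Relative to all genes, jasmonate signalling (-0.90, percentile 0), responsive defence (-1.07, percentile 0.01), green shoot tissue (-0.90, percentile 0) and root hair genes (-0.72, percentile 0.41) stood low, and phosphate starvation (0.41, percentile 100) and ethylene genes (0.27, percentile 99.4) stood high, with 1 of 13 (SQD1) and 1 of 20 (EIN2) called higher. Among random lists matched also on length, an alternative added after seeing the data, the ethylene list lay at percentile 68.3, and jasmonate biosynthesis (0.79), indole glucosinolates (1.71), auxin (1.61) and the endodermis (99.95) moved to the outer ends, so these placements depend on the matching. ALMT1 was higher in coi1-2 by 1.19 (interval 0.88 to 1.60), as was the ABC transporter gene ALS1, also by 1.19. With TMM factors both were below 2-fold, ALMT1 at 0.90 and ALS1 at 0.90. The Al resistance list as a whole did not stand apart (0.04, percentile 49.13), with 3 of 16 members higher and 1 lower.

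The difference between the genotypes' Al responses, which the series is about, could only be described, because no residual degree of freedom is left for a test. It exceeded 1 log2 unit with a counting interval that excluded 0 in 1227 genes toward a higher ratio in coi1-2 and in 334 toward a lower one; with TMM factors the split turned to 479 and 755, and with the length trend also removed it was 364 and 425. LOX4, a lipoxygenase of jasmonate synthesis, was read at 8.68 RPKM without and 1.80 with Al in Col, and at 1.46 and 3.06 in coi1-2, a difference of 2.86 (interval 2.08 to 3.63). AT2G17660 (2.86), ERF53 (2.88) and CBF4 (2.83) also differed upward, and AT2G01422 (-3.53), AT4G12510 (-3.43) and CBF3 (-3.33) downward. Green shoot tissue (percentile 0), cytokinin (-0.81, percentile 0) and root hair genes (-0.72, percentile 0.36) stood below all genes, and phosphate starvation (0.47, percentile 100), tubulin (0.17, percentile 99.3) and jasmonate biosynthesis genes (0.41, percentile 98.7) above. With the length trend removed, the tubulin list lay just below. Few members were called: 3 of 13 of green shoot tissue (RBCS1A, LHCB1.1 and LHCB2.2), 3 of 12 of cytokinin (ARR6, ARR3 and ARR4) and 2 of 8 of root hairs (EXPA18 and PRP3) downward. Upward were 3 of 13 of phosphate (SQD1, PLDP2 and PS2), 3 of 22 of tubulin (MAP65-2, MAP65-3 and EB1C) and 4 of 12 of jasmonate biosynthesis (LOX4, ACX1, AOC1 and OPCL1). Of these, ARR3, ARR4, PS2, EB1C, AOC1 and OPCL1 were named after their values were seen. The bootstrap intervals of root hairs and jasmonate biosynthesis included 0. Members were also called in lists whose median did not stand apart. Of Al resistance genes 5 of 16 were called upward and 0 downward (percentile 78.94), and of touch and wound genes 5 of 14 upward and 1 downward (percentile 95.24). Over all genes 7.0% were called upward and 1.9% downward, without scaling factors. Among lists matched also on length, tubulin (79.64) and jasmonate biosynthesis (96.65) no longer lay at the outer ends, and touch and wound (99.37), endodermis (99.44) and evening clock genes (0.40) did. The difference shares libraries with each genotype comparison: cytokinin genes stood low here and high in coi1-2 without Al, and jasmonate biosynthesis genes the other way round, and part of each mirror image follows from the libraries without Al, which both comparisons share.

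Library composition differed with Al. Reads from organelle genes made up 0.900% and 1.88% of the Col libraries without and with Al and 0.808% and 1.22% of the coi1-2 libraries, and the 10 most read transcripts took 8.16%, 11.1%, 9.06% and 10.3%. In Col the shortest decile of genes by transcript length had a median log2 ratio of 0.45 and the longest decile -1.58; in coi1-2 these were 0.18 and -0.97. Without Al the genotypes differed little along length (-0.02 and 0.09), and with Al the medians ran from -0.32 to 0.76.

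**Figure D4:**
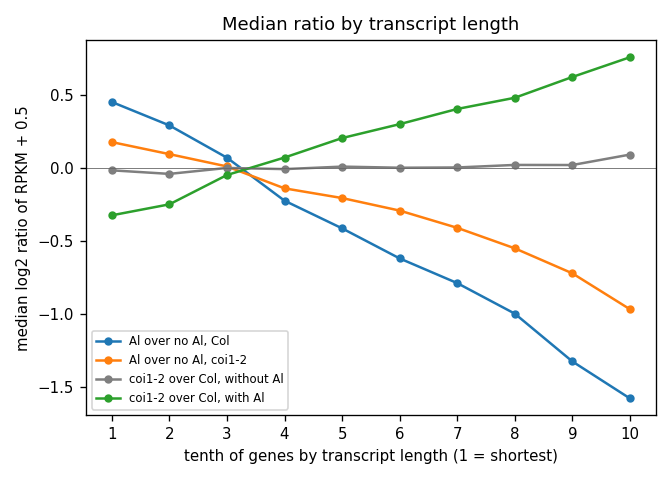
Median log2 ratio of RPKM + 0.5 in deciles of genes ordered by transcript length, for Al in each genotype and for coi1-2 over Col in each treatment, 1 library per group. The Col line runs from 0.45 in the shortest decile to -1.58 in the longest, and the line for genotype without Al stays between -0.04 and 0.09.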

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

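The choice to look at scaling and length for the genes given here was made only after the result was seen. In 6 genes the ratio was called higher with Al in Col and lower in coi1-2, or the reverse, past the size rule in both; with 1 library per group the difference between genotypes was not tested. EXPA12, an expansin, had a log2 ratio of 1.83 in Col and -1.11 in coi1-2, a difference of -2.94, from 5, 24, 24 and 9 reads in Col without and with Al and coi1-2 without and with Al. AT5G04120, annotated as a phosphoglycerate mutase family gene, had 2.42 and -3.62, a difference of -6.04, from 14, 81, 41 and 0 reads, at least 13.2-fold lower in coi1-2 against a floor of 3 reads. AT3G16660 had 1.17 and -1.66, a difference of -2.82, from 32, 67, 6 and 0 reads; against that floor it was at least 1.94-fold lower in coi1-2, short of 2-fold, and the counting interval of the difference included 0. AT1G53887 had 1.28 and -1.17, a difference of -2.46, and AT4G04692 had 1.41 and -1.12, a difference of -2.53. CRK10, a receptor-like kinase, went the other way, with -1.29 and 1.31, a difference of 2.60, from 128, 42, 53 and 139 reads. With TMM factors 1 of these 6 genes was still called in opposite directions, AT5G04120, and with TMM factors and the length trend removed 3 were, EXPA12, AT4G04692 and AT5G04120. The log2 ratios kept opposite signs in 6 of the 6 with TMM factors and in 5 with the length trend also removed.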

How the results depend on the processing

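The settings with the length trend, alone, with TMM factors or as an edgeR offset, loci with 1 isoform listed, and lists matched on length were chosen only after the result was seen. The others were planned. No paired analysis was possible because each group has 1 library and the labels carry no replicate numbers, though the Al test held genotype as a term, and for the same reason no library could be left out of a test with residual degrees of freedom; the planned variants of limma-trend as the main test did not apply, since read counts were given. Each result was counted once per alternative setting, so 1 gene or list can be counted several times. Of such pairs for the counts and variance shares that answer a comparison, 146 stayed within 1.5 times of the main value and 47 did not. For named genes and list medians 1651 pairs were labelled the same and 60 moved. In 87 pairs a named gene fell below the size rule, at most 29 of them under any 1 setting. In 2 pairs a list median changed sign. A list median was labelled the same when it stayed within its bootstrap interval over members, which is wide for some lists. A change of sign was counted only for lists outside the central 95% of random lists and for named genes past the size rule. Where a value moved, the cause was not tested, except that a stricter rule or filter takes fewer genes by construction.

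With TMM factors the genes higher and lower with Al were 3881 and 3596 in Col and 2585 and 2571 in coi1-2, those higher and lower in coi1-2 with Al 532 and 815, the differences of response 479 and 755, and the shared genes 2168 and 1964. With median-of-ratios factors these were 4043 and 3472, 2597 and 2563, 441 and 935, 419 and 850, and 2205 and 1934. With the length trend removed, 846 genes were higher and 170 lower in coi1-2 with Al, and 193 differences of response were downward. Of lists outside the central 95% of random lists, 2 medians then changed sign, ethylene for coi1-2 over Col with Al (-0.0092) and tubulin for the difference (-0.0127). With TMM factors and the length trend removed, 2746 genes were lower with Al in Col and 2199 in coi1-2, 1557 in both, 392 were higher and 372 lower in coi1-2 with Al, and 364 differences were upward and 425 downward. With the whole counting interval beyond the threshold, 1269 genes were higher with Al in Col, 1072 higher and 2451 lower in coi1-2, 69 higher and 82 lower in coi1-2 without Al, 277 and 90 with Al, and 162 and 69 for the difference. A pseudocount of 1 gave 776 genes higher in coi1-2 with Al, and a filter of 5 RPKM 162 without Al.

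For the tests, DESeq2 called 2515 genes that fell with Al, and 3 higher and 13 lower in coi1-2. Size factors of DESeq2 in edgeR gave 11 genes higher in coi1-2, the length offset 34 lower, and the model without Al, which counts the Al effect as error, 0 and 0. Limma-trend on log2 RPKM called 2541 genes that rose with Al. Genes of few reads are limited: ALMT1 without Al rests on 1 and 3 reads, and MATE and STOP1 could not be compared. Whether depth or the restriction to unique reads lies behind the few reads was not tested.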

Other observations

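The families in the paragraph on glutathione transferases were chosen after their values were seen, and the tests of library scaling for the length trend, of time of day, and of both corrections together were chosen only after the result was seen; the density bin of the coverage test was not fixed beforehand.

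Among 291 annotation terms with 10 to 200 genes, the term toxin metabolic process held 43 genes, of which 42 are named as glutathione S-transferases, enzymes that conjugate glutathione to reactive compounds. Of its 41 tested members 26 rose with Al and 7 fell by edgeR (24 and 9 with the length offset). GSTF2 was read at 152.0 and 238.0 RPKM without Al and 6726 and 5626 with Al in Col and coi1-2, and rose by 5.53, GSTU22 rose by 6.46 and GSTF6 by 6.28, while GSTU28 fell by 3.80 and GSTF14 by 3.65. Relative to all genes the term's median was 1.64 higher in Col and 1.04 in coi1-2; the term was picked for its values, so no comparison with random lists is given. All 10 genes of the term fluid transport are aquaporins of the PIP and TIP families, channels for water; 5 fell with Al and 3 rose by edgeR (6 and 3 with the length offset). GAMMA-TIP fell by 1.28, PIP2B by 1.54 and DELTA-TIP by 1.27, and TIP1;3 rose by 2.25. DELTA-TIP was read at 479.9 and 209.8 RPKM in Col without and with Al and at 482.2 and 91.9 in coi1-2. The difference between genotypes was not tested. The term tRNA aminoacylation for protein translation was also picked after its values were seen. Of its 46 tested members 22 fell and 3 rose by edgeR, but with the length offset only 8 fell and 3 rose.

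Long transcripts were lower in the Al libraries. Library scaling or a few abundant genes would move all lengths alike, but the shortest and longest deciles of genes parted by 2.03 in Col and 1.14 in coi1-2 (log2), and with GC content in the model the length slope kept 1.008 and 1.012 times its size, which argues against both. Loss of the 5' ends of long transcripts, as in partly degraded RNA, may contribute. At 40 to 80 reads per kb the median coverage of transcripts of at least 2000 nt was lower with Al by 10.07 points in Col (-10.07) and 2.86 in coi1-2 (-2.86). The test asked for a fall of at least 5 points in both genotypes, and only Col reached it. Coverage is given without position along the transcript, so it cannot show which end was lost. At 20 to 40 reads per kb the values were -7.48 and -3.72 and at 80 to 160 -6.13 and -2.55, so the reading was the same in all 3 bins. Degradation and an Al response that favours short transcripts cannot be told apart here, since every library with Al shows the trend and no library is replicated.

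More genes differed between coi1-2 and Col with Al than without. The length trend between the Al libraries and library scaling were each not the whole cause, since the count with Al was still 2.117 times (1016 against 480) and 2.941 times (1347 against 458) that without; with both removed together it was 1.721 times (764 against 444). A smaller Al response of most Al-responsive genes in coi1-2 may account for part: with both removed, the median signed difference of response was -0.223 over 5071 genes (bootstrap interval over genes -0.247 to -0.204), just past the bound of -0.2 set beforehand, and 64.0% of genes were smaller in coi1-2. Under the other scalings, added after this value was seen, it ran from -0.452 to -0.232, and rising genes alone gave 0.07 with only the length trend removed. At 40 to 80 reads per kb, median coverage of transcripts of at least 2000 nt was 73.05% in Col with Al and 79.55% in coi1-2 with Al. Without Al it was 83.12% and 82.41%. Whether COI1, a milder exposure or handling of the coi1-2 plants, or more degraded RNA in Col with Al lies behind the smaller response stays open with 1 library per group.

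Photosynthesis genes were higher in the Al libraries, of roots. Shoot tissue in those libraries may account for this, but the test largely restates the pattern. It counted photosynthesis genes that were higher, and its 44 genes include the green shoot genes already given. A TMM-scaled ratio above 1 was found for 100% of 44 nuclear photosynthesis genes in Col and 90.91% in coi1-2. Among genes matched to them it was 68.1% and 62.5%. With the length trend also removed the shares were 93.2% and 84.1%, against 50.04% and 49.87%. Levels in Col with Al ran from 0.380 RPKM for PSBP-1 to 288.3 for LHB1B2, and 19 of 20 plastid-encoded genes were also higher in each genotype (17 of 20 with the length trend also removed). The test would come out alike if Al induced these genes in roots, which was not separated from shoot tissue. Another time of day at harvest cannot be told apart, as the clock lists parted by -0.478 in Col and -0.231 in coi1-2 but only 1 morning gene was measured beside 6 evening genes.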
